A study of Mus musculus with 8 samples.

How the data were processed

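RNA was measured by sequencing in 8 mouse brain endothelial cell samples, 4 titled WT and 4 titled KO, with replicate numbers taken from the titles. The labels conflict with one another. The titles name a wild type and a knockout, the organism is mouse and the tissue is brain, while the treatment labels name control and USP9X siRNA and the design text describes a human brain microvascular endothelial cell experiment with Wnt3a stimulation. The deposited table holds mouse gene symbols under column names that match the titles, so the groups are called WT and KO here, and whether Usp9x was deleted or silenced, and whether Wnt3a was added, is left open. Per the labels' protocols, RNA was extracted with TRIzol and libraries were made with a stranded poly(A) kit.

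The deposited table gives expected counts per gene symbol, in whole numbers, which the authors made with RSEM per the submitters' processing notes. Those notes also name DESeq2 and the human build hg38, without versions. The aligner, the mouse build and the annotation are not given in the sources used here, so no coordinates are printed. The deposited counts sum to between 15522319 and 18502821 per sample and their median-of-ratios size factors range from 0.927 to 1.12, so they were treated as unnormalised counts. The table has 54532 entries, of which 23572 are at 0 in every sample, 105 repeat an earlier symbol and 27 carry a symbol that a spreadsheet had turned into a date (0.196% of counts). Date entries stayed in the library totals. Of all entries, 98.7% had a symbol in GENCODE M21, which was used only for transcript length, GC content and genomic span.

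KO was compared with WT with edgeR 4.0.16 in R 4.3.3, using the quasi-likelihood test on TMM-normalised counts after filterByExpr, which left 15695 genes. P-values were adjusted by the Benjamini-Hochberg method and the threshold was an adjusted p of 0.05. Standard errors of log2 fold changes were derived from the quasi-likelihood F statistics. Levels are CPM, counts scaled to a common library size with TMM factors, as mean ± SD over 4 libraries. Gene lists were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, with an estimated correlation and fry as alternatives, adjusted over 33 lists. Of 662 list entries, 657 matched a symbol in the table, 4 matched through another symbol and 1, Hbb-b1, did not match.

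The lists, tests and named genes were fixed before the data were examined. The rule named Usp9x, 8 genes in every case (Axin2, Lef1, Apcdd1, Cldn5, Plvap, Mfsd2a, Slc2a1 and Ctnnb1), and the 12 genes with the largest log2 fold change in each direction. Those 24 had to pass the threshold, reach a mean CPM of 1 in a group, have every KO library on the same side of every WT library, and not be predicted or clone-named. Up to 4 members with the smallest p were named for each list, and some of these are not reported here. Other members that passed, and members of 5 lists added after seeing the data, were chosen after their values were seen.

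Alternatives were DESeq2 1.42.0, limma-voom, DESeq2 size factors or upper-quartile factors in edgeR, no low-count filter, a filter of CPM of at least 1 in 4 samples, stricter thresholds, leaving out each library, a block of adjacent sample numbers, a Y-linked expression term, and 1 surrogate variable from sva 3.50.0. Removal of a per-library trend on transcript length, removal of trends on length and GC content, and leaving out WT 4 and KO 5 together were added after seeing the data. Transcript length was that of the longest protein-coding transcript of a symbol where there was one, and 99.4% of the genes tested had a value. The trend was a lowess curve with a span of 0.3.

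The procedure was tested on simulated counts for 15695 genes with 200 of them changed. The edgeR test recovered 40.3% of the smallest, 65.7% of the middle and 81.8% of the largest changes (1.5, 2 and 4-fold), with 9.42% false calls. With an added length trend, false calls rose to 41.7% and came to 6.25% once the trend was removed. Simulated genes varied independently of each other, and a share of false calls depends on how many genes change. These shares therefore do not carry over to the real counts. Replicates are separate samples per the labels, but nothing says whether they came from separate animals, so p-values measure the spread between these samples, which may be technical. Figures were drawn with matplotlib 3.10.9.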

Results

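Gene expression was measured by RNA sequencing in brain endothelial cell samples from mouse, 4 titled WT and 4 titled KO, to ask how loss of Usp9x, an X-linked deubiquitinase, alters transcription in brain vessels and Wnt signalling in particular. Total counts ran from 15522319 in KO 3 to 18502821 in WT 4. Across genes, Pearson's r between log2 CPM profiles was 0.970 to 0.983 within KO, 0.972 to 0.983 within WT and 0.952 to 0.979 between the groups, where genes are not independent replicates. The profile of WT 4 was as close to some KO libraries as to its own group. Its r was 0.979, 0.976, 0.967 and 0.967 with KO 1, KO 3, KO 5 and KO 8. With WT 2, WT 6 and WT 7 it was 0.980, 0.972 and 0.975. WT 4 and KO 5 stood apart in having 2086 and 2171 genes at 1 to 5 counts, against 4377 to 6826 in the other libraries. Y-linked genes summed to 73.5, 61.8 and 107 CPM in WT 2, WT 6 and WT 7 but 2.27 CPM in WT 4, against 5.28 to 39.1 CPM in KO, so sex composition was partly confounded with group. Xist was at 107 and 213 CPM in WT 2 and WT 4, at 2.43 and 5.42 CPM in WT 6 and WT 7 and at 75.9 to 524 CPM in KO, so some libraries held both Xist and Y-linked RNA.

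Usp9x was at 97.5 ± 3.75 CPM in WT and 78.7 ± 7.26 CPM in KO (SD, n = 4), which left KO at 80.7% of WT. The KO libraries stood at 74.9, 87.7, 80.9 and 71.1 CPM, and all were below the WT libraries at 97.6, 93.1, 97.0 and 102 CPM. The log2 fold change was -0.31 ± 0.08 (SE, edgeR adjusted p = 0.0389), and an exact two-sided permutation test of the CPM values gave p = 0.0286, the smallest that 4 against 4 samples allow. The edgeR call was lost with no low-count filter (adjusted p = 0.0612), a block of adjacent sample numbers (0.0827), a Y-linked term (0.159), and every single library left out except KO 3 (0.0540 to 0.0972), with the log2 fold change at -0.34 to -0.26. The table gives a single count per gene. If an exon was deleted, transcripts lacking it still count, and the level does not measure how much intact Usp9x RNA was left. If Usp9x was silenced by siRNA, as the treatment labels have it, the level would stand for the RNA left, at 80.7% of WT. Usp9x has a transcript of 11887 nt, and 510 well expressed genes of similar length had a median log2 fold change of -0.33. With the trend on transcript length removed, an alternative chosen after seeing the data, Usp9x was at 0.04 ± 0.08 (adjusted p = 0.827).

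**Figure D1:**
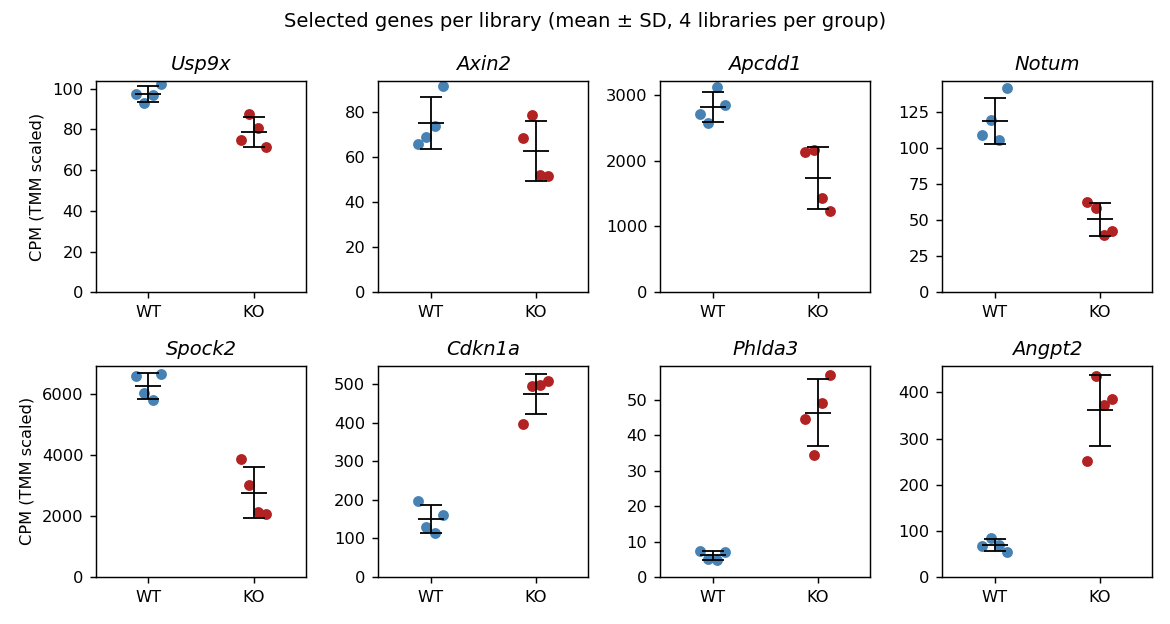
CPM (y axis, TMM scaled) of 8 genes in each WT (blue) and KO (red) library, with the mean and SD of 4 libraries in black. Usp9x, Apcdd1, Notum and Spock2 were lower and Cdkn1a, Phlda3 and Angpt2 higher in every KO library, while the Axin2 values of the groups overlapped.

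Between KO and WT, 1737 of 15695 genes passed the threshold, 983 higher and 754 lower in KO, and 4542 had an unadjusted p under 0.05. Of these, 114 rose and 75 fell by at least 2-fold. In 2824 genes (18.0%, against 2.86% by chance) all KO libraries lay on the same side of all WT libraries. The largest rises were in Eda2r, a p53-induced death receptor (log2 fold change 3.87 ± 0.30, 1.24 ± 0.138 to 18.2 ± 7.28 CPM, adjusted p = 0.000175), Fam110c (3.57 ± 0.65), the stress cytokine Gdf15 (3.56 ± 0.67) and Olfr1318 (3.34 ± 0.81). Fam110c, Gdf15 and Olfr1318 were each under 0.2 CPM in WT. They were followed by Esm1, a proteoglycan of sprouting endothelium (3.15 ± 0.21, 7.92 ± 1.52 to 70.3 ± 19 CPM), the p53 target Phlda3 (2.93 ± 0.20, 6.07 ± 1.37 to 46.3 ± 9.48 CPM), Ccdc184 (2.87), the non-coding RNA Pvt1 (2.72), Ly6i (2.48), Snx20 (2.45), the metallothionein Mt2 (2.44) and Angpt2, the Tie2 ligand that loosens vessels (2.39 ± 0.18, 68.9 ± 12.4 to 361 ± 77.4 CPM). The level of Ly6i is uncertain because close paralogs share its reads.

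The largest falls were in the recombinase Rag1 (-2.15 ± 0.62, near the detection limit at 1.72 CPM in WT), the matrix proteins Fbln2 (-1.81 ± 0.21, 149 ± 43.0 to 42.4 ± 9.43 CPM) and Tnc (-1.74 ± 0.16, 27.0 ± 5.24 to 8.05 ± 0.750 CPM), Gdap10 (-1.64), Snx29 (-1.61), Frmpd3 (-1.61), Efcc1 (-1.60), Msx3 (-1.60), the complement regulator Cfi (-1.58), Asxl3 (-1.49), the sphingosine phosphatase Sgpp2 (-1.47) and the receptor tyrosine kinase Ret (-1.45 ± 0.18, 76.7 ± 12.2 to 28.0 ± 7.81 CPM). With the length trend removed, 11 of the 12 that rose and 9 of the 12 that fell still passed, and Mt2 (2.11), Rag1 (-1.93), Frmpd3 (-1.37) and Asxl3 (-1.14) did not. With the Y-linked term 9 and 7 of them passed, and Olfr1318 (4.08), Ly6i (2.47), Efcc1 (-1.52) and Msx3 (-1.41) did not pass either. Without WT 4 and KO 5, 9 and 6 passed, and Cfi (-1.53) was not among them.

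Fold change followed transcript length. Genes higher in KO had a median transcript length of 1814 nt and genes lower in KO one of 6317 nt, against 3025 nt for all genes tested. Each library was also given a slope, per doubling of length, of its log2 CPM less the gene's mean over the 8 libraries. This slope differed by -0.158 between KO and WT, with an SD of 0.0341 in both groups and no overlap (n = 4, exact two-sided permutation p = 0.0286, the smallest possible). Such slopes are relative to the mean library, so their signs carry no meaning apart from that difference. The slope on GC content did not differ detectably (KO minus WT 0.000378 per percentage point, exact two-sided permutation p = 0.971). With the length trend removed, 651 genes passed, 458 higher and 193 lower, of which 526 were in the original set with the same sign. The share of higher genes among those that passed was 56.6% before and 70.4% after. Without WT 4 and KO 5, 504 genes passed, 308 higher and 196 lower, and with a Y-linked term in the model 318 passed. Leaving out single libraries brought the count to 570 without KO 5, 805 without WT 2, 890 without WT 7 and 906 without WT 6.

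**Figure D2:**
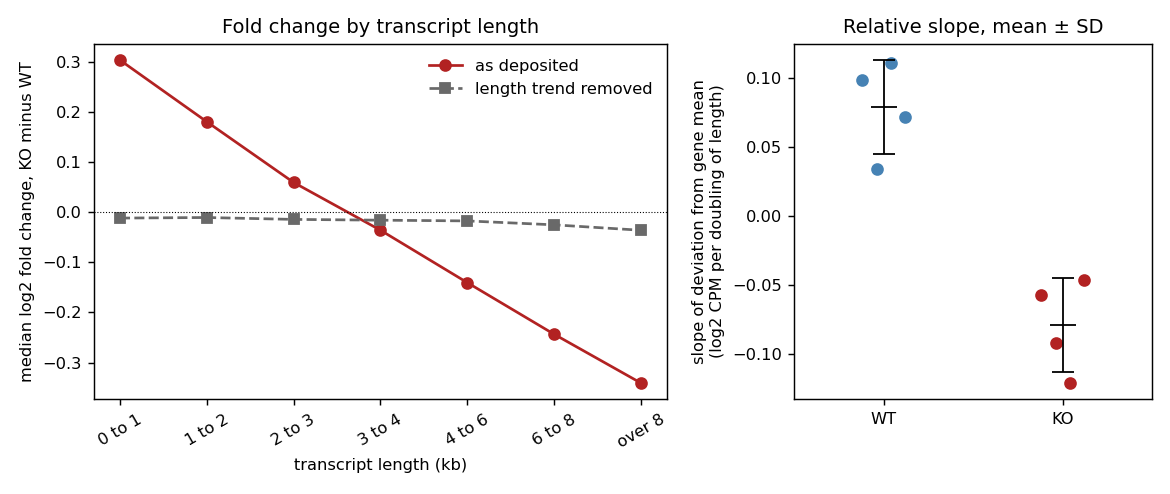
Left, median log2 fold change between KO and WT (y axis) for genes in bins of transcript length in kb (x axis), as deposited and with the per-library trend removed. Right, slope on log2 transcript length of each library's log2 CPM less the gene's mean over all 8 libraries, with mean and SD of 4 libraries, where every KO slope was below every WT slope and the groups differed by -0.158.

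Several targets of canonical Wnt signalling were lower in KO. Of 24 Wnt target genes measured, 5 fell, 1 rose and 18 did not pass (6 fell and 1 rose when adjusted over the list alone). Notum, a secreted Wnt deacylase, fell from 119 ± 16.2 to 50.7 ± 11.4 CPM (-1.23 ± 0.16, adjusted p = 0.00265), and Nkd1, a feedback inhibitor, from 326 ± 13.9 to 183 ± 38.5 CPM (-0.84 ± 0.13, adjusted p = 0.00663). Apcdd1, a Wnt inhibitor induced in brain endothelium, fell from 2810 ± 229 to 1736 ± 473 CPM (-0.69 ± 0.18, adjusted p = 0.0309), and Znrf3 (-0.56 ± 0.12) and Tnfrsf19 (-0.49 ± 0.11) fell too. Myc rose (0.45 ± 0.13). Axin2 was at -0.26 ± 0.15 (adjusted p = 0.285), Lef1 at -0.05 ± 0.09 (adjusted p = 0.734) and Ctnnb1, which encodes beta-catenin, at -0.09 ± 0.09 (adjusted p = 0.551). The list as a whole was lower by camera (median -0.21, adjusted p = 0.00546; adjusted p = 0.474 with an estimated correlation). With the length trend removed 2 members fell, Notum (-1.33) and Nkd1 (-0.77), while Apcdd1 was at -0.37 ± 0.17 (adjusted p = 0.245). The Y-linked term left 2 members past the threshold and leaving out WT 4 and KO 5 left 3, with list medians of -0.19 and -0.23. Apcdd1 was then at -0.77 ± 0.22 and -0.65 ± 0.21 (adjusted p = 0.0954 and 0.103).

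Among 29 Wnt receptors and transducers, 3 fell and none rose (6 when adjusted over the list alone). They were the ligand Wnt5a (-0.71 ± 0.14), the Wnt7 co-receptor Reck (-0.43 ± 0.11) and the kinase Gsk3b (-0.32 ± 0.08), with Bcl9 next at -0.38 ± 0.11 (adjusted p = 0.0541). The list also holds ligands such as Wnt5a and negative regulators such as Gsk3b, so its direction does not tell whether Wnt signalling fell. The list was lower by camera (median -0.30, adjusted p = 0.00151; adjusted p = 0.474 with an estimated correlation), and none of its members passed with the length trend removed, where the median was -0.16.

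Several genes of the blood-brain barrier fell in KO. Of 29 measured, 5 fell and none rose (12 when adjusted over the list alone). Spock2, a proteoglycan of the barrier matrix, fell from 6259 ± 424 to 2766 ± 840 CPM (-1.18 ± 0.19, adjusted p = 0.00656), Abcb1a, the P-glycoprotein efflux pump, from 608 ± 72.0 to 378 ± 93.9 CPM (-0.69 ± 0.16), and the organic anion transporter Slc22a8 from 846 ± 47.8 to 546 ± 127 CPM (-0.63 ± 0.15). The junction genes Ocln (-0.45 ± 0.12) and Jam2 (-0.36 ± 0.10) also fell. The tight junction gene Cldn5 was at -0.15 ± 0.12 (adjusted p = 0.461), the lipid transporter Mfsd2a at -0.35 ± 0.13 (adjusted p = 0.103) and the glucose transporter Slc2a1 at 0.10 ± 0.15 (adjusted p = 0.690). The list was lower by camera (median -0.34, adjusted p = 3.81e-05; adjusted p = 0.607 with an estimated correlation), and 2 members fell with the length trend removed, 1 with the Y-linked term and 1 without WT 4 and KO 5, with list medians of -0.31, -0.43 and -0.27.

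Of 15 genes of leaky or fenestrated endothelium, 4 rose and none fell (7 higher and 2 lower when adjusted over the list alone), namely Esm1, Angpt2, the apelin ligand Apln (1.21 ± 0.13, 579 ± 75.8 to 1339 ± 194 CPM) and the lipase anchor Gpihbp1 (1.26 ± 0.22). With the length trend removed 4 members rose. Plvap, which forms the diaphragms of fenestrae, was at -0.25 ± 0.22 (adjusted p = 0.50). Camera gave a median of 0.41 (adjusted p = 0.0180; adjusted p = 0.343 with an estimated correlation). Of 28 angiogenesis and tip cell genes, 7 rose and 2 fell (7 and 3 when adjusted over the list alone). Besides Esm1, Angpt2 and Apln, Adm rose by 1.31 ± 0.18, and the receptor genes Tek (-0.67 ± 0.10) and Flt1 (-0.40 ± 0.11) fell. This list did not pass as a group (adjusted p = 0.754), with a median of -0.14 and a mean of 0.28.

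Targets of p53 and apoptosis genes rose in KO, with the smallest camera p of the 33 lists. Of 22 genes measured, 13 rose, none fell and 9 did not pass (15 when adjusted over the list alone). Besides Eda2r and Phlda3, the cell cycle inhibitor Cdkn1a rose from 150 ± 36.6 to 474 ± 52.7 CPM (1.66 ± 0.16, adjusted p = 0.000785) and the pro-apoptotic Bax from 58.8 ± 1.43 to 117 ± 15.6 CPM (0.99 ± 0.10, adjusted p = 0.000931). The list median was 0.54 (camera adjusted p = 1.76e-08; adjusted p = 0.0216 with an estimated correlation). It was the only list of the 33 to pass with an estimated correlation. With the length trend removed 12 members rose, with the Y-linked term 8, and without WT 4 and KO 5 also 8.

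Of 28 proliferation genes, 10 rose and none fell (19 when adjusted over the list alone), among them the mitotic gene Birc5 (0.92 ± 0.12, 16.9 ± 2.04 to 32.0 ± 3.43 CPM), thymidylate synthase Tyms (0.82 ± 0.13), Ube2c (0.78 ± 0.14) and Cdk1 (0.60 ± 0.12). The list median was 0.46 (adjusted p = 5.49e-08; adjusted p = 0.474 with an estimated correlation). With the Y-linked term 1 member passed, but the median was 0.36 and the list still passed camera (adjusted p = 7.95e-05), and with the length trend removed 6 passed and the median was 0.43. Oxidative phosphorylation genes had 4 of 24 higher (10 when adjusted over the list alone), led by Cox5a (0.48 ± 0.09) and Sdhb (0.31 ± 0.07). Their median was 0.26 (adjusted p = 1.04e-05; adjusted p = 0.458 with an estimated correlation), and none of them passed with the length trend removed, where the median was 0.05.

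**Figure D3:**
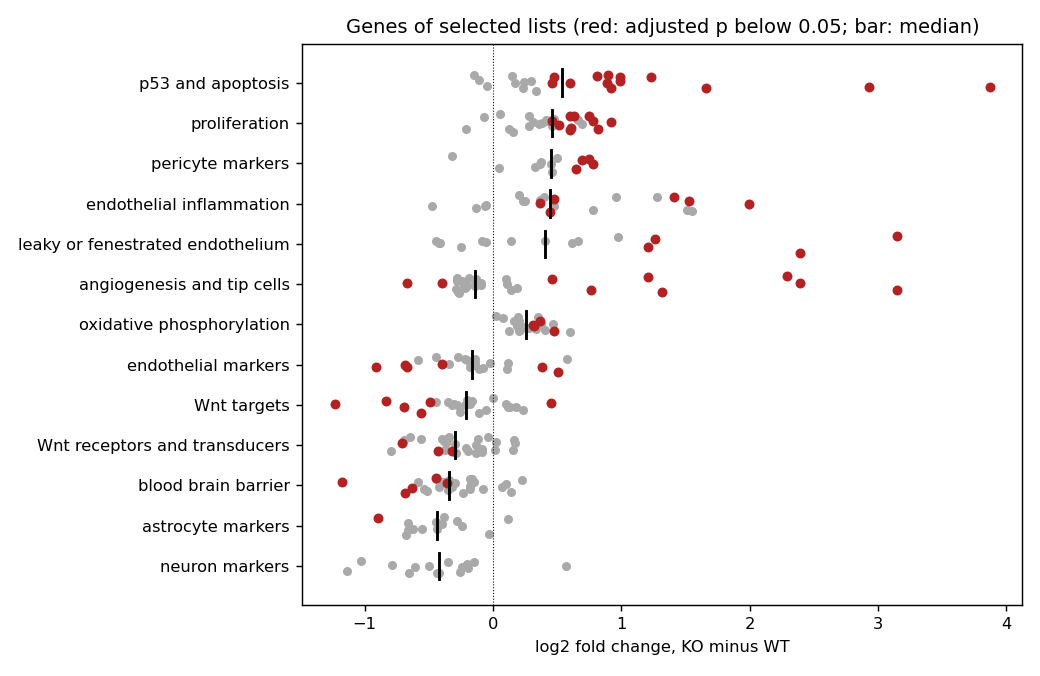
Log2 fold change of each gene of 13 lists (x axis), KO against WT, with genes at an adjusted p below 0.05 in red, others in grey and a bar at the list median. The p53 and apoptosis list had 13 of 22 genes in red, all above 0, and the blood-brain barrier list 5 of 29, all below 0.

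Inflammatory genes of endothelium had 6 of 21 higher and none lower (9 higher and 1 lower when adjusted over the list alone), among them the NF-kappaB subunit Relb (0.48 ± 0.10), the chemokine Cxcl1 (2.0 ± 0.42), Nfkbia (0.44 ± 0.10) and Nfkb2 (0.36 ± 0.10). Their median was 0.44 (adjusted p = 0.00116; adjusted p = 0.343 with an estimated correlation). Of 24 hypoxia and glycolysis genes, 6 rose (6 when adjusted over the list alone), including Adm, Hmox1 (0.48 ± 0.09), Ldha (0.60 ± 0.11) and Pgk1 (0.44 ± 0.10), with a median of 0.17 (adjusted p = 0.0241; adjusted p = 0.343 with an estimated correlation). Of 24 immediate early genes, which also respond to tissue handling, 5 rose (7 rose and 1 fell when adjusted over the list alone), led by Dusp1 (0.63 ± 0.12), with a median of 0.32 (adjusted p = 0.00199; adjusted p = 0.474 with an estimated correlation). In the interferon list 2 of 28 rose (1 when adjusted over the list alone), Bst2 (0.80 ± 0.08) and Cxcl10 (1.53 ± 0.45), with a median of 0.31 (adjusted p = 0.0303; adjusted p = 0.667 with an estimated correlation). In the cholesterol synthesis list 2 of 20 fell (2 when adjusted over the list alone), including Lss (-0.77 ± 0.18), with a median of -0.25 (adjusted p = 0.00116; adjusted p = 0.458 with an estimated correlation). Once the length trend was removed, 3 inflammatory, 2 hypoxia and glycolysis, 2 immediate early and 2 interferon genes passed, with list medians of 0.38, 0.08, 0.23 and 0.24. No cholesterol synthesis gene then passed, but the list median was -0.29 and Lss was at -0.66 ± 0.19 (adjusted p = 0.0748). Hmox1 (0.30, adjusted p = 0.0791), Pgk1 (0.29, 0.132), Nfkbia (0.26, 0.187) and Cxcl10 (1.30, 0.128) were then no longer past the threshold. With the Y-linked term, 1 gene passed in each of the lists of inflammatory, hypoxia and glycolysis, immediate early and interferon genes, at list medians of 0.39, 0.22, 0.32 and 0.38. Without WT 4 and KO 5, 2, 4, 1 and 1 genes passed in the same order, at list medians of 0.40, 0.17, 0.32 and 0.13.

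Marker lists of cell types had medians on both sides of 0, and none passed with an estimated correlation. Of 22 endothelial markers 4 fell and 2 rose (5 and 2 when adjusted over the list alone), with Ptprb at -0.92 ± 0.14, Tek, Abcb1a and Flt1 lower and Egfl7 (0.38 ± 0.09) and Emcn (0.51 ± 0.12) higher. Their median was -0.16 (adjusted p = 0.0228; adjusted p = 0.667 with an estimated correlation). Of 12 pericyte markers 4 rose and none fell (6 when adjusted over the list alone), namely Vtn (0.65 ± 0.12), Higd1b (0.78 ± 0.14), Ndufa4l2 (0.69 ± 0.13) and Kcnj8 (0.75 ± 0.14). Their median was 0.46 (adjusted p = 0.00101; adjusted p = 0.474 with an estimated correlation). Astrocyte markers had 1 of 14 lower, the water channel Aqp4 (-0.90 ± 0.19; 5 when adjusted over the list alone), with a median of -0.44 (adjusted p = 0.0180; adjusted p = 0.667 with an estimated correlation). No neuron marker of 15 passed (0 when adjusted over the list alone), with a median of -0.42 (adjusted p = 0.0433; adjusted p = 0.667 with an estimated correlation). In the synapse list 1 of 24 fell (0 when adjusted over the list alone), Bsn (-1.21 ± 0.32), with a median of -0.41 (adjusted p = 0.0125; adjusted p = 0.667 with an estimated correlation). Of 11 blood cell genes 3 fell (5 when adjusted over the list alone), the haemoglobin genes Hba-a2 (-1.33 ± 0.22), Hbb-bt (-0.95 ± 0.20) and Hbb-bs (-0.52 ± 0.13), whose near-identical copies share reads. Their median was -0.52 (adjusted p = 0.0300; adjusted p = 0.546 with an estimated correlation). Several of the lower medians moved close to or above 0 with the Y-linked term, which brought astrocyte markers to -0.03, neuron markers to -0.10, the synapse list to 0.01, oligodendrocyte precursor markers to 0.17 and oligodendrocyte markers to 0.56. Pericyte markers were then at 0.48 and endothelial markers at -0.19. That term also turned Ddx3y, a Y-linked gene, higher in KO (1.62 ± 0.32, adjusted p = 0.0421), so it is no clean correction for sex. Without WT 4 and KO 5 those lower medians moved further below 0 instead. Astrocyte markers were at -0.69, neuron markers at -0.71 and the synapse list at -0.62. Oligodendrocyte precursor markers were at -0.59 and oligodendrocyte markers at -0.35, with pericyte markers at 0.57 and endothelial markers at -0.15. With the length trend removed, 2 endothelial and 3 blood cell markers were lower and 4 pericyte markers higher. Higd1b (0.47, adjusted p = 0.0857) and Ndufa4l2 (0.42, 0.150) were not among these, while Cspg4 (0.75, 0.0292) was. Aqp4 and Bsn, at -0.76 and -0.78, did not pass (adjusted p = 0.0525 and 0.179), and Egfl7 was at 0.17 (0.282). No endothelial marker was higher with the length trend removed, with the Y-linked term or without WT 4 and KO 5.

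The other lists did not pass by camera. Median log2 fold changes of cell type markers were -0.39 for 14 microglia genes (Cx3cr1 fell), 0.25 for 9 smooth muscle genes (Myl9 rose), -0.20 for 12 fibroblast and meningeal genes (0 passed), -0.47 for 10 oligodendrocyte precursor genes (Ptprz1 fell), -0.19 for 10 oligodendrocyte genes (0 passed) and 0.40 for 12 choroid plexus genes (Rarres2 rose). When adjusted over the list alone, 1, 1, 0, 1, 0 and 0 of these passed, in the same order. The Notch and arterial list had 3 of 18 lower, Gja5 (-0.79 ± 0.17), Notch1 (-0.71 ± 0.16) and Sema3g (-0.60 ± 0.16), and the same number passed when adjusted over the list alone. None of its members was lower with the Y-linked term, and 1 was higher, Mgp (0.80 ± 0.14, adjusted p = 0.0326). The list of TGF-beta and BMP targets had 3 of 22 higher and 1 lower (3 and 1 when adjusted over the list alone), including Tgfbr2, which fell (-0.61 ± 0.12). The YAP and TAZ targets had 2 of 19 higher, Ctgf (1.34 ± 0.18) and Cyr61 (0.73 ± 0.10), and Tgfb2 lower (2 higher and 1 lower when adjusted over the list alone). The basement membrane list had Timp1 higher and Fn1 (-0.84 ± 0.15), Lama5 and Agrn lower of 28 (2 higher and 3 lower when adjusted over the list alone). The ubiquitin system list had 4 of 30 lower, including Usp9x and Huwe1 (-0.47 ± 0.08), and Uchl5 higher (5 lower and 1 higher when adjusted over the list alone). The astrocyte reactivity list had 3 of 19 higher and Osmr lower (4 higher and 1 lower when adjusted over the list alone), and the microglial activation list had 1 of 18 higher, Lgals3 (2.31 ± 0.43; 1 when adjusted over the list alone). None of 5 sex-linked genes passed (0 when adjusted over the list alone). With the length trend removed, 1 gene was lower and 0 higher in the ubiquitin list, where Huwe1 was at -0.08 (adjusted p = 0.625). Notch1 (-0.41), Sema3g (-0.50), Tgfbr2 (-0.34), Tgfb2 (-0.29), Timp1 (0.57), Lama5 (-0.44), Agrn (-0.37), Osmr (-0.64), Uchl5 (0.39), Cx3cr1 (-0.75), Ptprz1 (-0.75) and Rarres2 (0.39) were then not past the threshold (adjusted p = 0.0512 to 0.301), while Gja5, Fn1, Myl9 and Lgals3 were. Ctgf and Cyr61 passed too, but the removal left their values unchanged at 1.34 ± 0.18 and 0.73 ± 0.10, so their passing is no test against the trend.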

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

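Each measure named in the report or below was checked in both groups for a library set apart from the other 3 by a gap that took most of the group's range, beyond Dixon's 95% critical value. Of 332 groups checked, 20 held such a library, where chance alone gives about 1 in 20. These checks were planned, and the genes of the added lists entered them after the data were seen. The values below are given without explanation.

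In KO 1, Cdkn1a stood at 396 CPM against 496 to 508 in the other KO libraries, Atf4 at 188 against 235 to 240, and Gars at 166 against 183 to 186. Gdf15 was higher there, at 3.27 CPM against 1.77 to 1.92, and the Notch and arterial list had a mean log2 CPM of 6.40 against 6.25 to 6.27. In KO 3, Aqp4 was at 63.1 CPM against 75.4 to 76.2, Lss at 11.7 against 14.5 to 15.1, Sdhb at 118 against 125 to 126 and Asxl3 at 0.985 against 1.09 to 1.11. In KO 5, Hyal1 was at 3.44 CPM against 4.38 to 4.57. In KO 8, Xist was at 524 CPM against 75.9 to 140, Sesn2 at 36.1 against 22.9 to 24.6, Nfkbia at 184 against 218 to 226 and Hba-a2 at 13.3 against 20.6 to 21.7.

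Among WT libraries, WT 4 had Manf at 97.2 CPM against 80.6 to 82.2 and a mean log2 CPM of the hypoxia and glycolysis list of 5.68 against 5.74 to 5.75. In WT 6, Sdf2l1 was at 7.28 CPM against 10.8 to 11, Timp1 at 6.39 against 11.4 to 11.9, and Mt2 had 0 counts, against 0.706 to 0.992 CPM in the other WT libraries. In WT 7, Bcl9 was at 23.1 CPM against 27.3 to 28.3.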

How the results depend on the processing

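Removal of length or GC trends and leaving out WT 4 and KO 5 together were chosen after seeing the data. Against 1737 genes (983 higher and 754 lower), DESeq2 gave 2771 (1307 lower), and no low-count filter gave 1180 lower. A block of adjacent sample numbers gave 1057 (545 higher), a Y-linked term 318 (168 and 150), length trend removal 651 (458 and 193), length and GC trend removal 690 (475 and 215), and leaving out WT 4 and KO 5 504 (308 and 196). An adjusted p under 0.01 left 266 (160 and 106), and a 2-fold limit 189 (114 and 75). Leaving out single libraries gave 570 to 1549 genes (349 to 799 higher and 221 to 750 lower). The other scalings, filters, voom and a surrogate variable stayed within 1.5 times of the total. Fewer samples or more terms in the model leave fewer degrees of freedom. On the same simulated counts, DESeq2 made 182 calls with 20.9% false, against 138 calls with 9.42% false for edgeR. Otherwise the cause was not tested. Pairing by adjacent numbers, as in the block, has no support in the labels, since the groups share no replicate numbers, and deviations of adjacent numbers correlated at -0.16 to 0.23. Usp9x was at -0.31 with no low-count filter (adjusted p = 0.0612), -0.31 with the block (0.0827), -0.29 with the Y-linked term (0.159), -0.0127 with length and GC trends removed (0.942) and -0.34 without WT 4 and KO 5 (0.105), and reversed to 0.0395 with the length trend removed (0.827). Leaving out single libraries gave -0.36 to -0.26, and only leaving out KO 3 kept an adjusted p under 0.05. Ddx3y, a Y-linked gene that is itself part of the Y-linked term, reversed to 1.62 ± 0.32 with that term and passed as higher in KO (adjusted p = 0.0421). The term therefore did not take out Y-linked expression cleanly. Of 18 lists, 1 passed with an estimated correlation and 11 with fry. Adjusted p was then 0.474 for Wnt targets, 0.474 for proliferation and 0.607 for barrier genes (0.104 with fry), while the p53 list passed under every alternative run. At this depth, genes under 0.2 CPM in WT, such as Gdf15, rest on few counts.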

Other observations

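The 5 gene lists tested here, the slope over markers of other cells, its version within lists and the test of a lower endothelial share were chosen after the results were seen. That test is the third of 3 forms run, since a standard error over genes ignored their correlation and 36 pairwise tests were too many to pass with 8 libraries. Of 19 genes of the elastic fibre and its matrix, 7 fell, none rose and 12 did not pass. This list and the other 4 each had an adjusted p = 0.247 with an estimated correlation. Mfap2, a microfibril protein, was at -1.40 ± 0.13 (SE, adjusted p = 0.000785), Ltbp4 at -1.41 ± 0.23, Fbln5 at -1.10 ± 0.20, Eln, which encodes elastin, at -0.95 ± 0.26 and Fbn1 at -0.80 ± 0.16, beside Fbln2 and Tnc. Their median was -0.59, and with the length trend removed it was -0.48 and 5 were lower. Targets of the stress factor Atf4 had 7 of 22 higher and none lower, including Atf4 itself (0.62 ± 0.10), the secreted glycoprotein Stc2 (2.31 ± 0.31), Eif4ebp1 (0.99 ± 0.16), asparagine synthetase Asns (0.90 ± 0.22) and Mthfd2 (0.96 ± 0.26), beside Gdf15 and Sesn2, of which Sesn2 is also in the p53 list. Chaperones of the endoplasmic reticulum had 3 of 20 higher, Sdf2l1 (1.06 ± 0.15), Manf (0.65 ± 0.08) and Creld2 (0.53 ± 0.12), and tRNA synthetases had 2 of 20 higher, Rars (0.56 ± 0.07) and Gars (0.41 ± 0.08). Lysosomal genes had 4 of 24 lower, Psap, Ctsh, Ctsf and Hyal1, and Neu1 higher.

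Of these lists, 4 passed camera (adjusted p = 0.000185 for elastic fibre, 0.00218 for Atf4 targets and chaperones, 0.00273 for synthetases) and lysosomal genes did not (adjusted p = 0.0863, but 0.0143 with the length trend removed, and 0.157 with an estimated correlation beside it). Of 35 splits of the 8 libraries into 4 and 4, as small a camera p came from 2 for elastic fibre genes, 2 for Atf4 targets, 5 for chaperones, 4 for tRNA synthetases and 7 for lysosomal genes, the real split included, so chance was not excluded for any of the 5. The smallest p of the other splits was 5.06e-06 for elastic fibre genes, against 3.70e-05 in the real split.

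Only the real split of the 35 gave as many as 1737 genes, and the highest other split gave 19. This argues against chance for the count of genes at 1 of 35, the smallest share that 35 splits allow. It does not tell Usp9x loss from sex composition or any other difference between the groups. The count of lists was 18 in the real split (1 of 35), but other splits gave 2 to 17 lists with a median of 12, so a camera call at the preset correlation is weak evidence for any single list here. For the proliferation list, 4 of the 35 splits gave as small a p (3.33e-09 in the real split, 2.42e-14 the smallest of the others), so chance was not excluded.

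The rise of the p53 and apoptosis list was weighed against 4 explanations. Only the real split gave as small a camera p (1 of 35, 5.32e-10 against 3.95e-06 for the next). That is the smallest share 35 splits allow, and the list stood out for the smallest p of 33 lists. The splits alone therefore do not exclude chance. The list median of 0.54 was 0.60 with the length trend removed, 0.66 with a Y-linked term and 0.59 without WT 4 and KO 5, and the list passed each time, which argues against transcript length, sex composition and the low-count libraries as its whole cause. The case against sex composition is the weaker one, since the Y-linked term also turned Ddx3y, a Y-linked gene, higher in KO (1.62 ± 0.32). A p53 response in KO cells is a candidate explanation, as a hypothesis found and tested on the same libraries. A difference in handling or dissociation between the groups stays open, since the labels give no batch or date. Immediate early genes rose too, but 8 of 35 splits gave as small a camera p for their list, so chance was not excluded for that rise.

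The shift by transcript length, with Usp9x among the long transcripts, may come from an effect on all RNA in a library, such as RNA integrity or library preparation. Over 93 markers of neurons, synapses, glia and choroid plexus the slope of log2 fold change per doubling of length was -0.23 (95% interval -0.30 to -0.15). The lists of pericyte, smooth muscle and fibroblast markers were not used for it. A permutation over these genes gave p = 1e-05, the smallest that 100000 permutations can give. Within lists the slope was -0.18 (permutation p = 8e-05), against -0.16 over all genes. The interval and both permutations took genes as independent, although markers correlate. They therefore do not measure the spread between libraries. The markers also bear on an effect on all RNA only if Usp9x loss was confined to endothelial cells, which the labels do not state. Genomic span had a coefficient of -0.00608 per doubling (95% interval -0.0101 to -0.00208, genes taken as independent) beside -0.15 for transcript length. This argues against an effect on transcription of long genes as the main source of the shift. A small part in that direction is not excluded. Usp9x followed the trend, at 0.0395 ± 0.0829 once it was removed, so its fall is no measure of Usp9x loss apart from that trend. If Usp9x was deleted, reads from undeleted exons or undeleted cells cannot be told apart from a small loss, since KO stood at 80.7% of WT and the table has no counts per exon. If it was silenced instead, that level would mean that most of the RNA was left.

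The fall of the Wnt target and barrier lists was weighed against length, a lower endothelial share and chance. With the length trend removed, the smaller of the 2 ratios of the new to the original list median was 89.3%, which argues against length as the whole cause, although calls fell from 5 to 2 lower genes in both lists. A lower endothelial share cannot be told from these values. Endothelial markers were lower (median -0.16), but their list shares genes such as Cldn5 and Abcb1a with the barrier list and Sox17 with the Wnt targets. Their median is therefore not independent of the falls to be explained, and 12 of 35 splits gave as small a camera p. Pericyte markers were higher (0.46), while 6 of 9 lists of other cell types had a median below 0 (4 with the Y-linked term). The SD of the shifts of those 9 lists was 0.31 against a median of 0.27 over splits (exact permutation p = 0.314). Chance was not excluded for either list as a whole, since 4 of 35 splits for Wnt targets (1.65e-03, against 4.53e-04 for the smallest other) and 10 of 35 for barrier genes (4.62e-06, against 7.96e-11) gave as small a camera p. Of single genes, Notum, Nkd1 and Spock2 passed with the length trend removed, with the Y-linked term and without WT 4 and KO 5. Slc22a8 (-0.63 ± 0.15) passed the first and had wider errors in the others, at -0.76 ± 0.17 (adjusted p = 0.0536) and -0.52 ± 0.17 (0.104). Notum, Nkd1 and Spock2 may respond to Usp9x loss, but they were picked because they passed these settings. None of the settings tests a lower endothelial share, which stays open for these genes too.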
